A study of Solanum lycopersicum with 18 samples.

How the data were processed

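The series holds 18 RNA-seq libraries of tomato leaves, 3 for each combination of line (MT, EX) and time (0, 4 and 12 h). Per the labels' protocols, plants grew in soil in a greenhouse with long days, total RNA was extracted with Trizol, and libraries followed a BGI500 protocol. Every library was assigned to its group by its labels. All 18 value columns of the deposited table matched the title of exactly 1 library each, with 0 left over. No label gives a batch, and the labels do not say whether replicates were separate plants.

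Per the file headers, the authors deposited 1 table of 23348 genes with an FPKM value per gene and library, rounded to 2 decimals. A second set of 18 FPKM columns in it was identical to the first and was not used. Per the file headers, the table also carries the authors' log2 ratios, p-values and q-values for comparisons of groups, and how these were computed is not given in the sources used here. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5 without their roles, and name no genome build. Per the deposited table, 22658 genes are known genes and 690 are transcript models added to the annotation. Gene identifiers were matched to a reference table of the assembly SLM_r2.1, which was used for names only. It held 21649 of the identifiers, and 1828 genes had a symbol, 1553 of them among the genes tested. Coordinates are those of the deposited table, whose build is not named. The counting is not stated to use strand, so overlapping and antisense genes, and members of gene families with near-identical sequences, are reported as uncertain. Such reads could be split between copies or lost.

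No count values were used here, so depth was estimated. In genes with 1 transcript of 350 to 1500 bases, low FPKM values fall on steps that correspond to whole fragments. These steps gave 16300000 to 18300000 fragments per library, with 92.7 to 96.1% of the low values within 0.1 of a whole fragment. The 10 most abundant genes held 8.27 to 12.12% of the FPKM of a library. No gene was at 0 in all libraries, and 18743 genes were above 0 in all of them. Libraries of a group shared at most 0.332% identical values, so none was counted as a repeat of another.

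The design fixed before the data were examined foresaw a count model, with limma on log2(FPKM + 1) in its place if the values were FPKM. Since the deposited unit is FPKM, that written fallback was used throughout, and no count model was run. Genes with a mean of at least 1 FPKM in at least 1 group were kept (17870). Values were transformed to log2(FPKM + 1), and limma 3.58.1 was fitted over all 18 libraries with 6 group means, so that all groups shared 1 estimate of the spread, with a mean-variance trend in the moderation (prior degrees of freedom 3.18). An alternative with robust moderation was looked at first and is kept as an alternative. The p-values, which cover both directions, were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The 9 comparisons were EX against MT at each time, 4 h and 12 h against 0 h in each line, and the interaction of line and time at 4 h and 12 h. The overlap of calls between comparisons is set beside the product of the list sizes divided by the genes tested. This product is not a chance level, since the fit takes 1 spread per gene for all comparisons. Genes with a small spread can thus be called in several of them.

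For the gene lists, 49 were fixed from gene symbols, and 46 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Most themes, among them markers of other tissues and of wounding, were set before the data were examined. The members and some themes were set once the table's symbols could be read, since it has no gene descriptions to match, but before any value of a named gene was looked at. Each list was also tested with a correlation estimated from the data and with limma's fry. Of 24 list calls with the preset correlation, 1 held with the estimated one.

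Genes named in the text were chosen by a rule. In each comparison of 2 groups they are the 5 highest and 5 lowest log2 fold changes among called genes with a symbol, a mean of at least 5 FPKM in the higher group and no overlap between the 3 libraries of each group. For up to 8 lists with an adjusted p under 0.05, the 2 called members with the largest change in the direction of the list are added. CBF1 is given throughout as the 1 gene matched of several cold and clock genes named before the data were examined. For interactions the rule is the same without the overlap condition, and for genes called at all 3 times it takes up to 5 per direction by their smallest change. Fewer are named where fewer qualified, and genes named outside the rule are said to be so. A gene the rule selects is not reported here.

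The fits and list tests were first tested on simulated data built on EX against MT at 0 h with 17870 genes. Over 5 simulations with 100 genes changed per size, 67.4% of changes of 1 log2 unit and 92.2% of changes of 2 were called, and on average 10.6 unchanged genes were called per simulation. Changes were planted only in genes with a mean log2(FPKM + 1) above 2, so these shares do not cover lower genes. A shifted list was found in 5 of 5 simulations with 0 of 195 other lists called. The simulated genes varied independently of each other, with the same spread in all groups. These simulations therefore cannot show how the tests behave where genes of a list are correlated or groups differ in spread. A scan of windows of 60 neighbouring genes found a planted window with 20 called genes in 20 of 20 trials. Random draws of as many genes as were called at 0 h held at most 12 calls in a window. A planted window this large could thus hardly be missed, and weaker gatherings were not tried.

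The replicate numbers of the labels were checked for pairing by the correlation of deviations from the group means. Of 21 same-numbered pairs in the comparisons of 2 groups, 11 correlated above 0.1. EX against MT at 12 h was the 1 comparison with all its pairs above that (0.568, 0.231 and 0.405), and there a fit with the replicate block called 22 genes against 24 without it. Alternatives were other scalings, filters, pseudocounts and thresholds, the replicate block, library weights, fits on the compared libraries alone, and leaving out libraries. Those that need counts could not be run. Principal components were computed on log2(FPKM + 1) of the tested genes. The work used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.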

Results

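Leaf transcripts were measured by RNA sequencing in 2 tomato materials, Micro-TOM (MT), a dwarf cultivar widely used in the laboratory, and Micro-TOM-EX (EX), whose suffix the labels do not explain. Leaves of each material were taken at 0, 4 and 12 h of the treatment, with 3 libraries per group and 18 libraries in all. The title places the series as a comparison of both materials under cold stress. The growth protocol states that both were kept in the cold for these times, whereas the stress label reads control for every MT library and cold for every EX library, the 0 h libraries included. If the stress label holds, the MT time course is an untreated one. In either reading the time of day moved along with the hours of treatment, and no clearly untreated libraries of the same hours were analysed here. The deposited values are FPKM (fragment numbers scaled to transcript length and library depth) for 23348 genes, and FPKM totals per library lay between 758518 and 833908. Depth was estimated from the steps between low FPKM values at 16300000 to 18300000 fragments per library, so no group was sequenced much more deeply than another. Nothing in the labels says that the 3 libraries of a group came from separate plants, and all p-values measure only the spread between these libraries, which may be technical.

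The libraries parted first by time. On the first principal component, which held 35.6% of the variance, all 6 libraries of 0 h lay between -55.8 and -33.1 and all 12 libraries of 4 h and 12 h lay between 11.3 and 36.6. The second component (18.4%) set library 1 of MT at 0 h (61.9) and library 1 of MT at 4 h (52.6) apart from the others, which lay between -40.7 and 14.3. Correlations between libraries of a group, across genes on the log2(FPKM + 1) scale, were lowest in MT at 0 h (0.934 to 0.950) and highest in EX at 4 h (0.984 to 0.988). The median SD of a gene within a group was 0.267 log2 units in MT at 0 h, 0.270 in MT at 4 h and 0.168 in MT at 12 h. It was 0.190 in EX at 0 h, 0.129 in EX at 4 h and 0.177 in EX at 12 h. The fit takes 1 spread per gene for all groups, so it may understate the spread of MT at 0 h and 4 h. Genes tested numbered 17870, and genes are called changed where limma's adjusted p was under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Every gene named here as called in a 2-group comparison had all 3 libraries of one group above all 3 of the other, an arrangement that chance gives in 10% of genes.

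**Figure D1:**
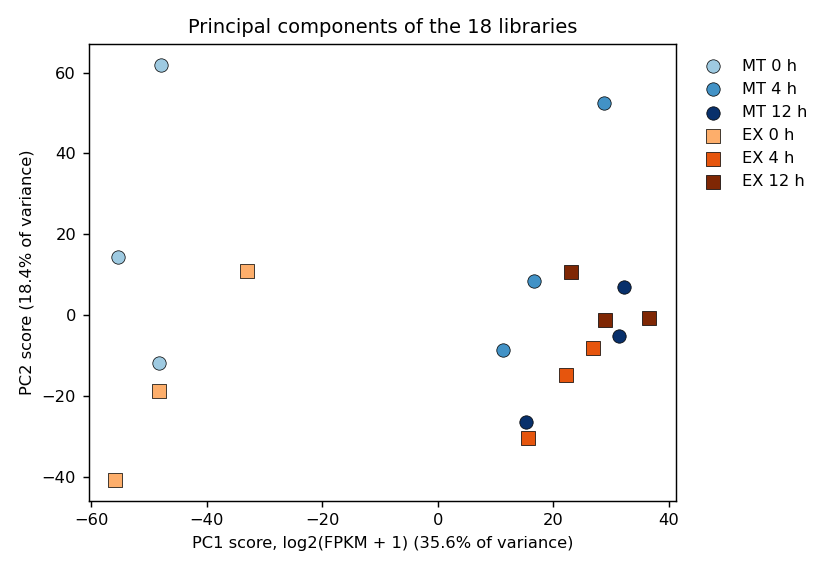
First against second principal component of log2(FPKM + 1), in component units, with 1 point per library and colours and markers for the 6 groups of line and time. The 0 h libraries lie between -55.8 and -33.1 on the first component and the 4 h and 12 h libraries between 11.3 and 36.6, and library 1 of MT at 0 h and library 1 of MT at 4 h stand highest on the second.

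The first comparison asked how EX leaves differed from MT leaves at 0 h, before any hours of treatment. GLB1, a class 1 non-symbiotic hemoglobin, stood at 31.4 ± 7.44 FPKM in EX and 0.147 ± 0.131 in MT (SD, n = 3 each; log2 difference 4.80, SE 0.29, adjusted p = 4.32e-07). The metallocarboxypeptidase inhibitor gene mcpi was at 178.5 ± 53.7 against 7.95 ± 4.90 FPKM (log2 4.43, adjusted p = 0.000905), and the defensin-like gene DEFL1 at 191.0 ± 45.6 against 28.9 ± 8.55 (log2 2.70, adjusted p = 0.00463). GABA-TP3, a transaminase of 4-aminobutyrate breakdown, went the other way, with 3.86 ± 0.930 FPKM in EX and 70.4 ± 37.9 in MT (log2 -3.73, SE 0.33, adjusted p = 2.38e-05). GLB1 (chromosome 7, 2965697 to 2967964), mcpi (1989154 to 1990602) and DEFL1 (2394475 to 2395559) lie within 1 segment of chromosome 7, from 1.3 to 4.6 Mb, where 45 of 193 tested genes were called at 0 h. GABA-TP3 lies on chromosome 12 (921679 to 927385).

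Further genes higher in EX at 0 h were ARPI (log2 2.96, adjusted p = 0.00799; chromosome 11, 13312544 to 13313544) and CAB5 (log2 1.91, adjusted p = 0.0455). CAB5 encodes a light-harvesting chlorophyll a/b-binding protein and read 990.8 ± 370.3 against 276 ± 135 FPKM. Lower in EX were AS1 (log2 -2.54, adjusted p = 0.00682; chromosome 6, 1237850 to 1242478) and the ethylene response factor gene ERF1 (log2 -1.74, adjusted p = 0.0438). The cyclin-dependent kinase inhibitor gene krp3 (log2 -1.56, adjusted p = 0.028) and ACO6 (log2 -1.45, adjusted p = 0.0365), whose enzyme makes ethylene from its direct precursor, were lower too. CBF1, a transcription factor gene of the cold response, was not called, with 119.8 ± 24.6 FPKM in EX and 73.6 ± 41.2 in MT (log2 0.87, adjusted p = 0.379). GLB1, mcpi, ARPI, DEFL1, GABA-TP3 and AS1 kept their calls when any 1 of the 6 libraries was left out. CAB5, ERF1, krp3 and ACO6 lost theirs without library 1 or 3 of MT or library 1 or 3 of EX, with adjusted p from 0.0545 to 0.178 over these genes and the sterol desaturase gene C5-SD. With the replicate block, CAB5 (0.0502), ERF1 (0.0556) and ACO6 (0.0516) lost their calls too. Reads of CAB5 may be shared with near-identical family members, so its level is uncertain.

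Of the gene lists, photosystem and light-harvesting genes stood higher in EX at 0 h as a set (22 tested, median log2 0.54, camera adjusted p = 7.74e-07), a call lost at adjusted p = 0.917 with an estimated correlation. CAB5 was the 1 member called, and 3 were higher when adjusted over the list alone. Sterol and glycoalkaloid genes (33 tested, median log2 0.18, adjusted p = 0.00688, but adjusted p = 0.917 with an estimated correlation) had 4 members called higher and none called lower (6 and 1 adjusted over the list alone). These included C5-SD (25.5 ± 4.13 against 11.9 ± 3.17 FPKM, log2 1.06, adjusted p = 0.036) and the sterol reductase gene DWF5-2 (log2 1.06, adjusted p = 0.029). The glycoalkaloid genes GAME6 (log2 0.92, adjusted p = 0.0206) and GAME17 (log2 1.04, adjusted p = 0.0256), named after their values were seen, were the others. Carotenoid synthesis (17 tested, median log2 0.19, adjusted p = 0.00332, but adjusted p = 0.917 with an estimated correlation) had 1 call, also 1 adjusted over the list alone: NXD1, a gene needed to form neoxanthin (37.8 ± 5.82 against 18.1 ± 3.04 FPKM, log2 1.03, adjusted p = 0.0113). Ethylene genes stood lower (30 tested, median log2 -0.32, adjusted p = 0.0491, but adjusted p = 0.917 with an estimated correlation), with 2 members called lower, ACO6 among them, and 4 called lower when adjusted over the list alone. Calvin cycle enzymes (7 tested, median log2 0.53, adjusted p = 0.0491) had 0 members called by limma, and 0 adjusted over the list alone. The last call was likewise lost, at adjusted p = 0.917 with an estimated correlation. With the replicate block, the Calvin cycle (0.0657) and ethylene lists (0.0539) also passed the threshold of 0.05 no longer. Without library 1 of MT at 0 h and library 1 of MT at 4 h, the Calvin cycle (0.358), ethylene (0.535) and sterol lists (0.106) did not pass. C5-SD lost its call without library 1 or 3 of either line, and DWF5-2 without library 1 or 3 of MT or 2 or 3 of EX (0.0641 to 0.115). NXD1 lost its call without library 1 of MT or library 1 or 3 of EX (0.0519 to 0.0646).

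Over all genes, 567 were called at 0 h, 175 higher and 392 lower in EX. Of these, 89 and 86 differed by at least 1 log2 unit. After division by median-of-ratios factors, which moved the median of all genes from log2 -0.096 to -0.007, the split was 209 higher and 152 lower. Without library 1 of MT it was 77 higher and 71 lower. The count was carried by which libraries entered: without library 1, 2 or 3 of MT it was 148, 3375 and 121, without library 1 or 3 of EX 85 and 94, and without library 2 of EX 473. With the replicate block 371 genes were called, and 193 without library 1 of MT at 0 h and library 1 of MT at 4 h. A fit on the 6 compared libraries alone called 25 genes, and there ARPI (adjusted p = 0.061), GABA-TP3 (0.0599) and AS1 (0.107) were not among them.

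**Figure D2:**
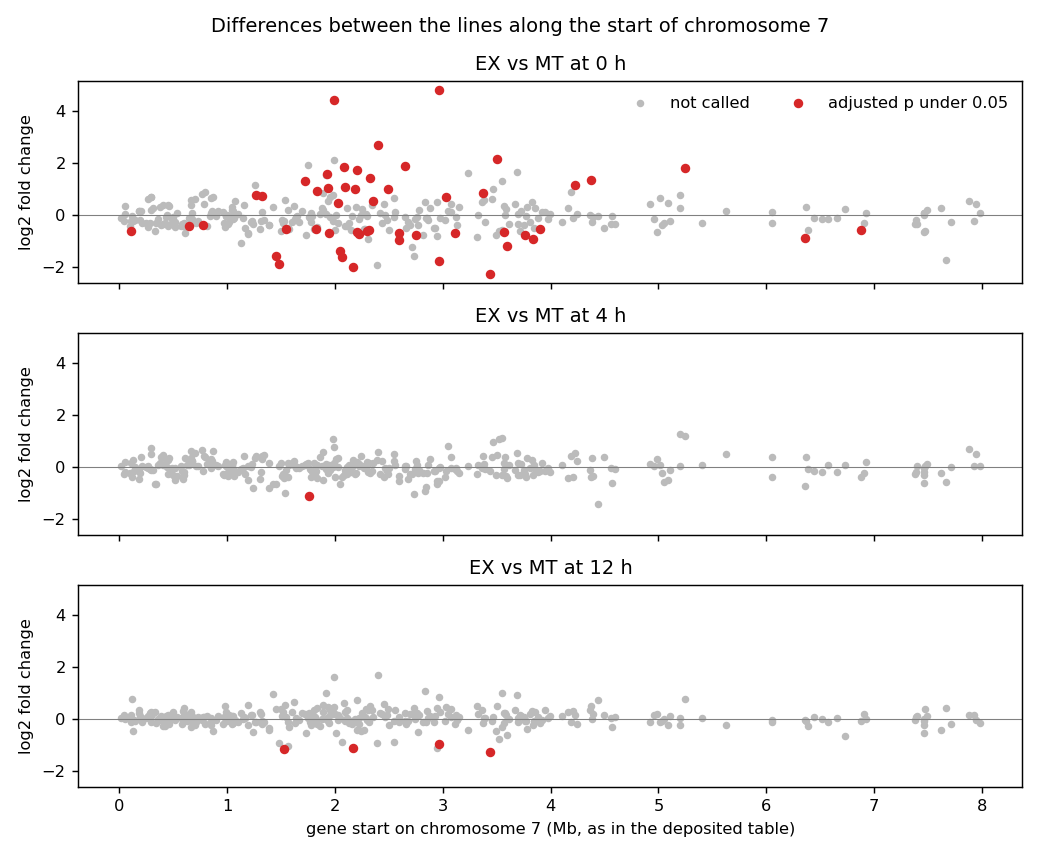
Log2 difference of EX against MT (vertical axis) for tested genes along the first 8 Mb of chromosome 7 (horizontal axis, Mb) at 0, 4 and 12 h, with called genes in red. Between 1.3 and 4.6 Mb, 45 of 193 genes were called at 0 h, 1 at 4 h and 4 at 12 h.

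At 4 h, EX leaves held more transcript of a pair of neighbouring glycoalkaloid genes. GAME17, a glycosyltransferase gene, was at 74.8 ± 9.30 against 31.2 ± 5.62 FPKM (SD, n = 3 each; log2 1.24, SE 0.22, adjusted p = 0.0282; chromosome 7, 57269493 to 57271197). GAME6, a cytochrome P450 gene, was at 9.07 ± 0.760 against 4.14 ± 0.989 (log2 0.98, adjusted p = 0.0348; 57246987 to 57249113). FESOD, an iron superoxide dismutase gene, was at 833.4 ± 34.7 against 391.6 ± 59.8 FPKM (log2 1.1, adjusted p = 0.0375; chromosome 6, 31007764 to 31010331). BR1 was lower in EX, at 108.7 ± 17.36 against 360.9 ± 116.4 (log2 -1.68, adjusted p = 0.0371; chromosome 9, 71577885 to 71579973). These were the only genes with a symbol that met the naming rule at 4 h. CBF1 was not called (25.3 ± 4.87 against 16.8 ± 2.94 FPKM, log2 0.55, adjusted p = 0.683). All 4 called genes kept their calls without library 2 of MT and lost them without any 1 of the other 5 libraries (0.0778 to 0.193). With the replicate block FESOD (0.0582) and BR1 (0.0756) lost theirs too.

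At the same time photosystem genes stood higher as a set (median log2 0.59, camera adjusted p = 1.02e-09), as did Calvin cycle enzymes (0.42, adjusted p = 0.0105). Both calls were lost, at adjusted p = 0.787 with an estimated correlation. Also higher were carotenoid synthesis (0.29, adjusted p = 5.19e-04) and sterol and glycoalkaloid synthesis (0.12, adjusted p = 0.0132). These calls too were lost, at adjusted p = 0.787 with an estimated correlation. Cytosolic ribosomal proteins stood lower (9 tested, median -0.39, adjusted p = 0.0105), a call likewise lost at adjusted p = 0.787 with an estimated correlation. Single members were called only in the sterol and glycoalkaloid list, GAME6 and GAME17, with 9 higher and 2 lower adjusted over the list alone. The other 4 lists had 0 calls by limma and, adjusted over the list alone, 0 apart from 1 lower in carotenoid synthesis. The ribosomal list also lost its call without library 1 of MT at 0 h and library 1 of MT at 4 h (0.467). In all, 53 genes were called at 4 h, 24 higher and 29 lower in EX, with 20 and 23 differing by at least 1 log2 unit. The count was 14, 504 and 26 without library 1, 2 or 3 of MT and 20, 19 and 13 without library 1, 2 or 3 of EX. More were higher than lower without library 1 or 3 of MT (8 and 6, 14 and 12) or library 3 of EX (7 and 6), and as many without library 1 of EX (10 and 10). The count was 35 with the replicate block (20 higher, 15 lower), 17 without the pair of MT libraries that stood apart, and 3 in a fit on the compared libraries alone.

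At 12 h, PEPC1, a phosphoenolpyruvate carboxylase gene, was the 1 gene that met the naming rule. It stood at 12.8 ± 3.51 FPKM in EX and 4.26 ± 0.777 in MT (SD, n = 3 each; log2 1.37, SE 0.24, adjusted p = 0.0308; chromosome 4, 663671 to 674893). CBF1 was not called, and its direction was not settled. Its mean was 34.6 ± 37.4 FPKM in EX, with 1 library at 77.8 and the others at 14.1 and 11.9, and 31.5 ± 13.5 in MT. The difference of mean log values was -0.28, and it was 0.08 and 0.19 without library 1 or 3 of EX. Pathogenesis-related genes stood higher in EX as a set (26 tested, median log2 0.20, camera adjusted p = 0.0224). It had 0 members called by limma, 1 called higher when adjusted over the list alone, and adjusted p = 0.753 with an estimated correlation. In all, 24 genes were called, 15 higher and 9 lower. An unadjusted p under 0.05 was found for 599 of the 17870 genes tested, a share below the 0.05 that no difference at all would give. PEPC1 lost its call without library 1, 2 or 3 of MT (0.228, 0.075 and 0.0991) or library 2 or 3 of EX (0.19 and 0.103). The count was 9, 10 and 10 without library 1, 2 or 3 of MT, and 15 and 14 without library 1 or 3 of EX. It split into 4 higher and 6 lower without library 2 of MT, 5 and 5 without library 3 of MT, and 7 and 7 without library 3 of EX.

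Genes that differed between the lines whatever the hour numbered 7, of which 6 were higher and 1 lower in EX (1.97e-04 and 3.20e-04 for independent lists). The numbers for independent lists are not a chance level here, since the comparisons share 1 spread per gene. LOC104647720 (chromosome 5, 53681013 to 53696285) was higher in EX at 0, 4 and 12 h by log2 1.88, 2.35 and 1.75. It read 7.04 ± 1.63, 8.50 ± 1.59 and 4.46 ± 1.49 FPKM against 1.15 ± 0.0945, 0.933 ± 0.690 and 0.587 ± 0.242 in MT (SD, n = 3 each). LOC104645110 (chromosome 12, 40404540 to 40404962) was higher by 1.51, 1.99 and 2.27, and was listed at 0 in all MT libraries at 12 h. The added transcript models BGI_novel_G000035 (chromosome 1, 47236425 to 47242217) and BGI_novel_G000544 (chromosome 10, 32402996 to 32404987) were listed at 0 in all 9 MT libraries. In EX the first read 1.36, 2.49 and 1.15 FPKM at 0 h, 2.19, 2.27 and 2.28 at 4 h and 2.19, 5.11 and 3.07 at 12 h. The second read 3.35, 2.57 and 3.04, then 1.53, 1.94 and 3.05, then 0.94, 2.07 and 1.56. BGI_novel_G000544 overlaps another added model, so its reads are uncertain. BGI_novel_G000581 (chromosome 11, 7052500 to 7053194) was higher by 1.37, 1.77 and 1.33. LOC101245171 (chromosome 6, 4786593 to 4792847) was the 1 gene lower in EX at all times, by log2 -1.67, -1.48 and -1.15. It stood at 5.06 ± 1.06, 5.32 ± 1.02 and 7.38 ± 1.78 FPKM against 18.4 ± 3.65, 16.7 ± 3.34 and 17.5 ± 3.15. LOC101255379 (chromosome 12, 66784207 to 66793732; log2 1.47, 1.45 and 1.24), named after its values were seen because the rule takes 5 per direction, overlaps a gene on the opposite strand and is uncertain.

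At 12 h the calls of 3 of these genes were lost in most fits with 1 library fewer, in which the log2 difference lay between -1.32 and -1.05 for LOC101245171, 1.59 and 1.995 for LOC104647720, and 1.175 and 1.53 for BGI_novel_G000581. LOC101245171 lost its call without library 1, 2 or 3 of MT (0.322, 0.227 and 0.0672) or library 1 or 3 of EX (0.222 and 0.256). BGI_novel_G000581 lost it without any 1 library except library 1 of EX (0.0526 to 0.209), and LOC104647720 without library 2 or 3 of either line (0.0569 to 0.0833). The count of 7 became 12 without library 2 of MT at 4 h, 4, 3 and 3 without library 1, 2 or 3 of MT at 12 h, and 4 without library 2 of EX at 12 h. It was 0 in limma fits on the compared libraries alone and 1 among genes with at least 5 FPKM in at least 3 libraries. Across genes, which are not independent replicates, the EX minus MT differences at 0 h and 4 h correlated at r = 0.48, those at 0 h and 12 h at -0.071 and those at 4 h and 12 h at -0.019.

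**Figure D3:**
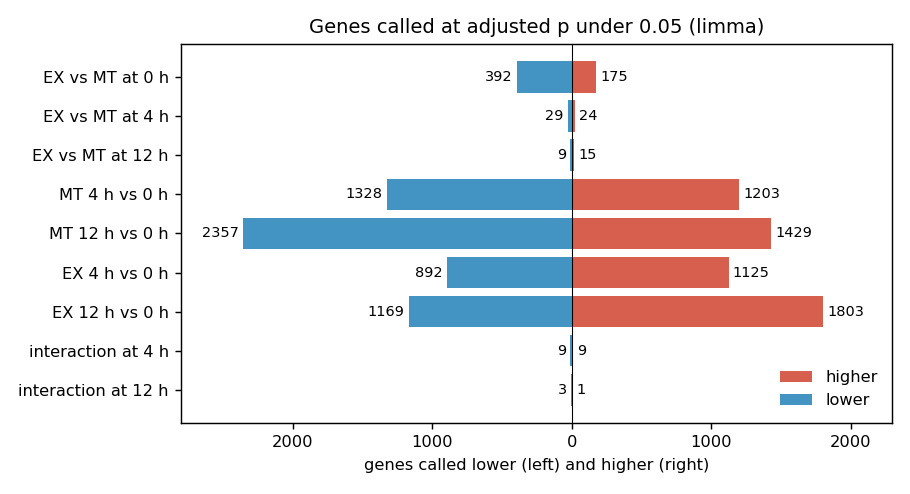
Number of genes called higher and lower (limma adjusted p under 0.05) in each of the 9 comparisons, with 1 pair of bars per comparison. The time courses hold between 2017 and 3786 called genes, the comparisons of lines 567, 53 and 24, and the interactions 18 and 4.

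The time course of MT asked which transcripts changed after 4 h and after 12 h of the treatment. At 4 h NR, a nitrate reductase gene (chromosome 11, 7173681 to 7178200), had risen from 5.88 ± 3.46 to 168.6 ± 91.6 FPKM (SD, n = 3 each; log2 4.65, SE 0.37, adjusted p = 1.55e-06). GLB1 rose from 0.147 ± 0.131 to 34.3 ± 12.2 (log2 4.90, adjusted p = 9.17e-08) and mcpi from 7.95 ± 4.90 to 140.2 ± 92.9 (log2 3.76, adjusted p = 0.000362). Both lie in the chromosome 7 segment in which the lines differed at 0 h. The gene ail (log2 4.45, adjusted p = 2.29e-06) and the CONSTANS-family gene CO1 (log2 3.43, adjusted p = 3.64e-06) also rose. GABA-TP3 fell from 70.4 ± 37.9 to 2.42 ± 0.395 FPKM (log2 -4.22, adjusted p = 1.4e-06). AS1 (log2 -2.34, adjusted p = 0.00161), SRG2 (log2 -2.36, adjusted p = 0.00978) and TGAS118 (log2 -2.57, adjusted p = 0.00313), which lies in the same segment, fell as well. The 3 MT libraries of 0 h also enter the comparison of lines at 0 h and both interactions. The changes of GLB1, mcpi, GABA-TP3 and AS1 rest on the same MT values of 0 h as their line differences, and are not separate findings. CBF1 (chromosome 3, 3714712 to 3715582) fell from 73.6 ± 41.2 to 16.8 ± 2.94 FPKM (log2 -1.88, SE 0.58, adjusted p = 0.0417). This call was lost without library 1 or 3 at 0 h (0.109 and 0.159) or any 1 library at 4 h (0.0685, 0.085 and 0.103). It was also lost with the replicate block (0.0585). SRG2 lost its call without library 1 at 0 h and library 1 at 4 h together (0.133).

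Heat shock proteins fell as a set in MT at 4 h (17 tested, median log2 -0.77, camera adjusted p = 0.00741), a call lost at adjusted p = 0.862 with an estimated correlation. Of its members 5 were called lower and none higher, and 9 and 0 adjusted over the list alone. The chaperone gene HSP90 fell from 7.46 ± 5.27 to 0.387 ± 0.177 FPKM (log2 -2.32, adjusted p = 0.00361) and Hsp90-1 from 143.3 ± 31.8 to 67.7 ± 17.1 (log2 -1.07, adjusted p = 0.0038). The list call was also lost without library 1 of MT at 0 h and library 1 of MT at 4 h (0.106), where Hsp90-1 lay at 0.0505. Other lists did not pass as sets but held called members. Auxin genes had 11 higher and 4 lower of 67 (14 and 4 adjusted over the list alone) and cytokinin genes 4 and 2 of 15 (5 and 2 adjusted over the list alone). Expansins with xyloglucan enzymes had 4 and 2 of 25 (8 and 3 adjusted over the list alone). CBF/DREB1 factors and regulators had 1 member called higher and 3 lower of 10, the same adjusted over the list alone (camera adjusted p = 0.954). Dehydrins and other cold-regulated proteins had 1 of 10 called in each direction (1 and 1 adjusted over the list alone; 0.842).

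At 12 h NR stood at 211.7 ± 20.7 FPKM in MT (log2 5.10, adjusted p = 4.45e-07; n = 3 each). TLOG1, whose product releases active cytokinin, rose from 20.7 ± 8.49 to 382.3 ± 146.5 (log2 4.14, SE 0.42, adjusted p = 1.04e-05; chromosome 4, 65331750 to 65335044). Psy1, a phytoene synthase gene of the carotenoid pathway, rose from 2.32 ± 0.262 to 53.1 ± 7.33 (log2 4.02, SE 0.24, adjusted p = 7.55e-08; chromosome 3, 4324965 to 4330008). GLB1 (log2 4.14, adjusted p = 3.26e-07) and AP2e, an AP2-type transcription factor gene (log2 4.01, adjusted p = 0.000117), rose too. BR1 fell from 1166 ± 471 to 125.4 ± 20.7 FPKM (log2 -3.12, adjusted p = 1.27e-05). The sterol desaturase gene CYP710A11 fell from 17.0 ± 0.0723 to 1.23 ± 0.556 (log2 -3.04, adjusted p = 1.64e-06), and GABA-TP3 to 9.86 ± 2.96 (log2 -2.58, adjusted p = 8.4e-05). A pair of xyloglucan endotransglucosylase genes with the symbol XTH9 also fell, gene ID 543916 by log2 -2.97 (adjusted p = 0.00291) and gene ID 101261784 by -2.56 (adjusted p = 0.0137). Reads shared between such near-identical genes leave their levels uncertain. The second lost its call without library 1 at 0 h (0.0682) or library 3 at 12 h (0.0547). CBF1 was not called at 12 h (31.5 ± 13.5 FPKM, log2 -1.11, adjusted p = 0.187), though it was without library 2 at 0 h (0.0484).

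Carotenoid synthesis rose as a set in MT at 12 h (17 tested, median log2 0.25, camera adjusted p = 0.00868), a call lost at adjusted p = 0.711 with an estimated correlation. It had 3 members called higher and none lower, also 3 and 0 adjusted over the list alone. Besides Psy1, the lycopene beta-cyclase gene LCY1 went from 20.9 ± 1.47 to 53.2 ± 4.46 FPKM (log2 1.31, adjusted p = 1.36e-06). The list call was also lost without the pair of MT libraries that stood apart (0.0515). Of 67 auxin genes 12 were called higher and 5 lower (15 and 5 adjusted over the list alone), and of the 10 CBF/DREB1 genes 1 in each direction. In all, 2531 genes were called in MT at 4 h (1203 higher, 1328 lower) and 3786 at 12 h (1429 higher, 2357 lower). At 4 h which direction held more calls was not settled. It was 1188 higher and 1006 lower without library 1 at 0 h, 1070 and 1034 without library 1 at 4 h, 999 and 795 without both, 302 and 201 in a fit on the compared libraries alone, and 1315 and 1302 with median-of-ratios factors. At 12 h the split was 1746 higher and 1867 lower after division by median-of-ratios factors. The 12 h count was 2507 without library 1 at 0 h, and 2271 and 2394 without library 1 or 2 at 12 h. Fits on the compared libraries alone called 503 genes at 4 h and 1478 at 12 h.

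The same question was asked of EX. At 4 h NR rose from 6.84 ± 2.02 to 186.9 ± 35.4 FPKM (SD, n = 3 each; log2 4.6, SE 0.37, adjusted p = 1.55e-06). The gene ail rose from 4.98 ± 2.01 to 169.6 ± 65.1 (log2 4.82, adjusted p = 1.07e-06) and TLOG1 from 6.95 ± 2.28 to 165.0 ± 31.1 (log2 4.4, adjusted p = 7.11e-06). PPCK1, whose kinase acts on phosphoenolpyruvate carboxylase, rose from 20.2 ± 13.6 to 286.9 ± 147.6 (log2 3.94, adjusted p = 3.98e-05). The gene fsm1, which encodes a MYB-type SANT protein, rose from 0.153 ± 0.133 to 16.9 ± 3.42 (log2 3.94, adjusted p = 6.81e-06). Of the 5 lowest genes of the naming rule, 4 encode xyloglucan endotransglucosylases, which remodel the cell wall. For tXET-B2 the fall was from 267.1 ± 66.6 to 12.8 ± 6.51 FPKM (log2 -4.35, adjusted p = 7.37e-05; chromosome 7, 63901555 to 63902817). XTH9 with gene ID 543916 fell by log2 -3.44 (adjusted p = 0.0014), XTH3 by -3.35 (adjusted p = 0.000908) and tXET-B1 by -3.19 (adjusted p = 0.0028), with reads possibly shared between the family members. BR1 fell from 1012 ± 263 to 108.7 ± 17.36 (log2 -3.19, adjusted p = 1.24e-05). CBF1 fell from 119.8 ± 24.6 to 25.3 ± 4.87 FPKM (log2 -2.20, adjusted p = 0.0223). The call was lost without library 2 or 3 at 0 h (0.0562 and 0.0736) or any 1 library at 4 h (0.0555, 0.0887 and 0.0536).

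As sets, cytokinin genes (15 tested, median log2 0.71, camera adjusted p = 0.00277) and auxin genes (67 tested, median log2 0.25, adjusted p = 0.00277) stood higher in EX at 4 h. These calls were lost, at adjusted p = 0.0941 with an estimated correlation for cytokinin and adjusted p = 0.819 with an estimated correlation for auxin. Heat shock proteins stood lower (17 tested, median log2 -0.39, adjusted p = 0.0257), a call lost at adjusted p = 0.999 with an estimated correlation. Of the cytokinin genes 4 were called higher and 1 lower (6 and 1 adjusted over the list alone), with LOG6, related to TLOG1, rising from 7.91 ± 0.956 to 66.4 ± 8.36 FPKM (log2 2.92, adjusted p = 3.14e-05). Of the auxin genes 13 were called higher and 3 lower (19 and 3 adjusted over the list alone). Among them were IAA4, a repressor of auxin-responsive transcription (19.9 ± 4.6 to 133.9 ± 28.5 FPKM, log2 2.69, adjusted p = 8.17e-06), and GH3-9, of the family that joins auxin to amino acids (log2 1.87, adjusted p = 4.56e-05). Of the heat shock genes 2 were called lower, and 3 adjusted over the list alone: HSP100/CLPB (log2 -0.76, adjusted p = 0.00248) and ER-SHSP (log2 -0.73, adjusted p = 0.0202), the latter near 1 FPKM and lost without library 1 or 3 at either time (0.0541 to 0.102). Expansins and xyloglucan enzymes did not pass as a set (camera adjusted p = 0.381), with 5 members called higher and 7 lower of 25 (7 and 9 adjusted over the list alone).

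At 12 h NR stood at 252.7 ± 25.4 FPKM in EX (log2 5.04, adjusted p = 4.35e-07; n = 3 each) and TLOG1 at 209.7 ± 41.3 (log2 4.75, adjusted p = 2.14e-06). The gene ail was at 132.5 ± 36.4 (log2 4.5, adjusted p = 1.34e-06) and PPCK1 at 313.8 ± 43.2 (log2 4.17, adjusted p = 1.7e-05). ERF1 rose from 1.59 ± 0.927 to 41.8 ± 13.4 (log2 4.06, adjusted p = 1.51e-05). SRG2 fell from 327.6 ± 122.5 to 26.9 ± 15.1 FPKM (log2 -3.63, adjusted p = 0.000402). As at 4 h, tXET-B2 (log2 -4.0, adjusted p = 1.19e-04), XTH3 (-3.16, adjusted p = 0.00113), tXET-B1 (-3.12, adjusted p = 0.00264) and BR1 (-3.04, adjusted p = 1.48e-05) stood lower. CBF1 was lower by log2 -2.26 (adjusted p = 0.0147), with single libraries at 14.1, 77.8 and 11.9 FPKM. It lost its call without library 3 at 0 h (0.0542) or library 1 or 3 at 12 h (0.0681 and 0.0837).

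Auxin genes stood higher as a set in EX at 12 h (median log2 0.24, camera adjusted p = 0.0199), a call lost at adjusted p = 0.970 with an estimated correlation. Of them 19 were called higher and 3 lower, also 19 and 3 adjusted over the list alone. IAA4 reached 281.5 ± 25.4 FPKM (log2 3.78, adjusted p = 2.16e-07) and GH3-9 94.4 ± 19.4 (log2 2.29, adjusted p = 5.09e-06). Photosystem and light-harvesting genes stood lower (median log2 -0.49, adjusted p = 6.76e-04), a call also lost at adjusted p = 0.970 with an estimated correlation. Of them 4 were called lower and none higher (6 and 0 adjusted over the list alone). The EX libraries of 0 h also enter EX against MT at 0 h, where this list stood higher, so the list calls are not separate findings. CAB12 fell from 542.9 ± 311.6 to 109.3 ± 27.9 FPKM (log2 -2.13, adjusted p = 0.037) and Cab-1D from 3292 ± 1741 to 741.9 ± 251.5 (log2 -2.03, adjusted p = 0.0464). Both light-harvesting genes may share reads with near-identical copies and lost their calls without library 1 or 3 at 0 h or any 1 library at 12 h (0.0623 to 0.178). In all, 2017 genes were called in EX at 4 h (1125 higher, 892 lower) and 2972 at 12 h (1803 higher, 1169 lower). The 4 h count was 1182 without library 1 at 0 h and 1343, 1233 and 1294 without library 1, 2 or 3 at 4 h. The 12 h count was 1782 and 1861 without library 1 or 3 at 0 h and 1742 without library 3 at 12 h.

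**Figure D4:**
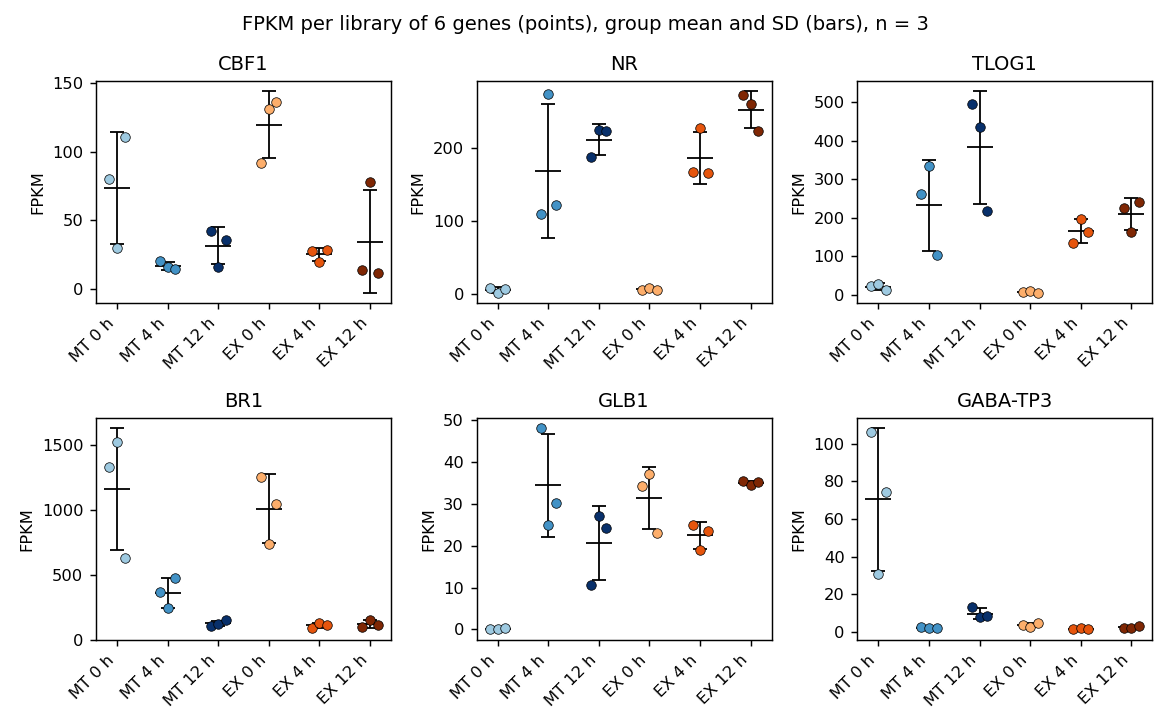
FPKM of CBF1, NR, TLOG1, BR1, GLB1 and GABA-TP3 (vertical axes) in each library of MT and EX at 0, 4 and 12 h, with points for libraries and the group mean ± SD (n = 3). NR rises from 5.88 to 168.6 in MT and from 6.84 to 186.9 in EX between 0 and 4 h, while GLB1 is near 0 only in MT at 0 h and GABA-TP3 is high only there (70.4).

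Both lines shared much of the time course. At 4 h, 639 genes were called higher in both lines and 575 lower in both, where independent lists would share 75.7 and 66.3, and 3 genes were called in opposite directions. At 12 h, 808 were higher and 757 lower in both (144 and 154 for independent lists), with 6 opposite. The numbers for independent lists are not a chance level, because 1 spread per gene entered the calls of both lines. Genes with a small spread could thus be called in both, though a shared spread does not favour the same direction over the opposite one. NR, TLOG1, ail, CO1, Psy1 and BR1 were among the genes called in the same direction in both lines at both times. Fold changes of the lines, which share no libraries, correlated across genes at r = 0.738 at 4 h and 0.664 at 12 h.

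Whether a change over time differed between the lines was tested as an interaction, the change in EX minus the change in MT. At 4 h GLB1 had the lowest value with a symbol, log2 -5.34 (SE 0.42, adjusted p = 1.29e-05). It went from 0.147 ± 0.131 to 34.3 ± 12.2 FPKM in MT and from 31.4 ± 7.44 to 22.5 ± 3.20 in EX (SD, n = 3 each). GABA-TP3 had the highest, 3.41 (SE 0.47, adjusted p = 0.00655), going from 70.4 ± 37.9 to 2.42 ± 0.395 FPKM in MT and from 3.86 ± 0.930 to 1.75 ± 0.316 in EX. Both values rest on the MT libraries of 0 h, as do the line differences of these genes at 0 h and their changes in MT. The call of GABA-TP3 was lost in a fit on the compared libraries alone (0.0597). In all, 18 genes were called, 9 in each direction, and 7 of them lie in the chromosome 7 segment, leaving 11 elsewhere. Expansins and xyloglucan enzymes changed less upward or more downward in EX as a set (25 tested, median log2 -0.34, camera adjusted p = 1.74e-04). This was the 1 list call that held, at adjusted p = 0.0421 with an estimated correlation. None of its members was called by limma (1161 of all 17870 genes had an unadjusted p under 0.05), and 4 were lower when adjusted over the list alone. XTH3 (log2 -2.98, adjusted p = 0.387) and tXET-B2 (-2.48, adjusted p = 0.512), picked after their values were seen, did not pass singly. The count of 18 became 37 and 34 without library 1 or 2 of MT at 0 h and 33 without library 2 of MT at 4 h. It was 11, 11 and 10 without library 1, 2 or 3 of EX at 0 h, 11 and 10 without library 1 or 3 of EX at 4 h, and 7 in a fit on the compared libraries alone.

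At 12 h, 4 genes were called, 1 higher and 3 lower. GLB1 again was among them (log2 -3.96, SE 0.42, adjusted p = 0.000861; 20.6 ± 8.81 FPKM in MT and 35.0 ± 0.494 in EX at 12 h, n = 3 each). The other 3, named after their values were seen, have no symbol. LOC101246665 (chromosome 1, 86628614 to 86633696) went from 3.94 ± 0.979 to 12.4 ± 3.54 FPKM in MT and from 60.2 ± 10.7 to 8.96 ± 3.89 in EX (log2 -4.11, adjusted p = 0.000861). LOC101266830 (chromosome 6, 14408402 to 14412111; log2 -2.52, adjusted p = 0.00898) reached 5.82 ± 3.31 in MT at 12 h. LOC101250115 (chromosome 5, 4521367 to 4525292; log2 2.03, adjusted p = 0.000861) stood at 12.0 ± 2.99 FPKM in MT at 0 h and 2.11 ± 0.375 in MT at 12 h. Photosystem genes (median log2 -0.66, camera adjusted p = 5.05e-08), Calvin cycle enzymes (-0.47, adjusted p = 0.0362), carotenoid synthesis (-0.24, adjusted p = 0.00977) and sterol and glycoalkaloid synthesis (-0.12, adjusted p = 0.024) had lower values as sets and ethylene genes higher ones (0.47, adjusted p = 0.024). These calls were lost, at adjusted p = 0.873 with an estimated correlation for the lists with lower values and adjusted p = 0.990 with an estimated correlation for ethylene. None of their members was called by limma, where 2940 of all 17870 genes had an unadjusted p under 0.05, and adjusted over the list alone 1 carotenoid gene was lower. The same lists were called in EX against MT at 0 h, each in the opposite direction, and none of them in EX against MT at 12 h. The 0 h libraries enter both tests, so these list calls are not separate findings. Without library 1 of MT at 0 h and library 1 of MT at 4 h, the Calvin cycle (0.256), ethylene (0.256) and sterol lists (0.244) did not pass. Median-of-ratios factors moved the median interaction of all genes at 12 h by -0.11, from 0.13 to 0.02, and ended the Calvin cycle call (0.0542). The count of 4 was 9 and 1503 (1036 higher, 467 lower) without library 1 or 2 of MT at 0 h, 8 without library 2 of EX at 12 h and 7 in a fit on the compared libraries alone.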

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

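All tests of explanations in this part were chosen after the results were seen, among them the choice of windows of 60 genes and the bounds of the chromosome 7 segment; the interaction tests themselves were set before the data were examined.

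Results are given here because the change over time differed between EX and MT by the interaction test. At 4 h, 18 genes were called, with GABA-TP3 at log2 3.41 and GLB1 at -5.34, and expansins and xyloglucan enzymes differed as a set (camera adjusted p = 0.000174, and adjusted p = 0.0421 with an estimated correlation). GABA-TP3 lost its call in a fit on the compared libraries alone (0.0597). At 12 h, 4 genes were called, with GLB1 at -3.96. As sets, photosystem and light-harvesting proteins (5.05e-08), Calvin cycle enzymes (0.0362), carotenoid synthesis (0.00977), ethylene genes (0.024) and sterol and glycoalkaloid genes (0.024) differed at 12 h with the preset correlation of camera. All 5 calls were lost, at adjusted p = 0.873 with an estimated correlation, or 0.990 for ethylene, and that of the Calvin cycle also with median-of-ratios factors (0.0542). The same 5 lists were called in the opposite direction in EX against MT at 0 h, and none of them in EX against MT at 12 h. Both tests use the same 0 h libraries, so these list calls are not separate findings. Of 100 splits of the samples drawn for each interaction, 7 gave at least as many calls at 4 h and 7 at 12 h, the real split included. The splits regrouped the lines at each time separately, so a lasting difference between the lines could enter them as an interaction. These shares therefore cannot decide about chance, which is not excluded for these counts. The highest of the other splits called 1808 genes at 4 h and 115 at 12 h, far above the real counts. Such counts may come from differences between the lines or from other structure among the samples.

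Genes called at 0 h were gathered on chromosome 7, where a window of 60 genes (1889772 to 2607821) held 22 calls, or 36.7% of its genes against 3.06% elsewhere, while 0 of 1000 random draws of as many genes reached that number (highest 12). Leaving out each library in turn left at least 9 calls in the window (fewest without library 3 of EX), so no 1 library carried all of them. A first form of this test was the ratio of the share called in the window to that over all genes. It fell to 2.4 without library 2 of MT and would have decided nothing. It was replaced after it was seen, with new bounds also set then. Calls in the window also follow the total number: without library 2 of MT they were 27, with 3375 genes called in all. No verdict on 1 stray library is therefore drawn. A candidate explanation is a sequence difference in this segment that was not the same in all MT plants. The EX minus MT differences at 0 h and 12 h, from other libraries, correlated across the genes of the window at r = 0.791. The highest of 1583 windows on other chromosomes was 0.692. This window was picked for its calls at 0 h, however, and the other windows were not picked. Any lasting difference between the lines there could give a higher correlation, so this does not tell sequence from expression. The window held 0 calls at 4 h and 1 at 12 h, and the correlation of 0 h with 4 h was 0.239. GABA-TP3 on chromosome 12 and LOC101250115 on chromosome 5 showed high MT values at 0 h outside the segment, so the segment leaves part of the pattern open. Reads with sequence variants, not used here, would decide between a difference in the plants and one in expression.

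More genes were called lower (392) than higher (175) in EX at 0 h. A few genes taking much of the FPKM is argued against as the whole source. The median log2 difference of all genes was -0.127 after scaling to the total without the 10 most abundant genes. It was -0.142 after scaling to the total of all genes, and -0.096 without either scaling. An offset over all genes in the FPKM scale cannot be told apart from a difference between the lines in the same direction over many genes, which was not tested. Lower calls went from 392 to 152 after division by median-of-ratios factors, but these bring the median of all genes near 0 (-0.007) in either case, so this decides nothing, and scaling to a common total, which does not centre the median (-0.142), gave 153 higher and 512 lower. Without library 1 of MT, 77 genes were called higher and 71 lower.

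CBF1 fell over time in EX and in MT at 4 h. Scaling of the libraries is argued against by the size of the factors, which lay between 0.959 and 1.088 under both other scalings. Such factors could not remove a fall of this size, so the rescaled fits were no separate test. In them the fall in EX at 4 h was log2 -2.18 where nearest to 0, and its call held. Time of day or handling at 0 h could account for it and cannot be told apart from cold, because the labels do not say clearly which libraries were untreated: in MT, whose stress label is control, the change at 4 h was -1.88. The same-strand neighbours LOC109119806 (log2 -2.69 in MT and -2.74 in EX at 12 h) and LOC101263186 (-3.02 and -3.78) also fell at 12 h.

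For each of the 7 comparisons of 3 libraries against 3, the 10 splits are too few for a share under 0.05, and 1 split, the real one, gave the most calls. The real and highest other counts were 567 and 393 for EX against MT at 0 h, 53 and 0 at 4 h, 24 and 0 at 12 h, 2531 and 630 for MT at 4 h, 3786 and 7 at 12 h, 2017 and 2 for EX at 4 h, and 2972 and 1 at 12 h. For the 7 genes called in the same direction at all 3 times, 1 of 100 splits, the real one, gave as many, and the highest other gave 0. That share was largely set in advance, since the other splits at 4 h or 12 h alone called 0 genes and so leave nothing to share. It is no evidence apart from the splits of single times, and chance is not excluded by it.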

How the results depend on the processing

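The alternatives of median-of-ratios and common-total scaling, the FPKM minimum of 5, robust variance, library weights, leaving out MT 0 h library 1 with MT 4 h library 1, and leaving out the chromosome 7 segment were chosen after seeing the data; the others were set before. DESeq2 size factors (in a count fit and for the lists), the DESeq2 Wald test and a CPM minimum of 5 need counts and were not run.

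No named gene that was called, and no called list, changed its direction under any setting tried for it. CBF1 in EX against MT at 12 h, which was not called, changed sign without library 1 or 3 of EX (0.08 and 0.19), and more genes were called higher than lower in EX against MT at 0 h under median-of-ratios scaling (209 and 152), without library 1 of MT (77 and 71) and in the fit on the compared libraries alone (14 and 11). Which direction held more calls also turned for EX against MT at 4 h with the compared libraries alone (2 higher and 1 lower), the replicate block (20 and 15), an adjusted p under 0.01 (9 and 7) and without the pair of MT libraries (9 and 8). It turned at 12 h with the compared libraries alone (12 and 13) and an adjusted p under 0.01 (4 and 6), and for the interaction at 12 h with library weights (2087 and 701); turns for MT at 4 h and without single libraries are in the report. Counts of called genes are given in the order of the report. All 10 counts stayed within 1.5 times under common-total scaling, log2(FPKM + 0.1), no filter and robust variance. Fits on only the libraries of the groups compared have fewer residual degrees of freedom. They called 25 genes for EX against MT at 0 h, 3 at 4 h, 503 in MT at 4 h and 1478 at 12 h. They called 7 and 7 for the interactions, and 0 at all 3 times by limma. The 7 counts that moved all use MT libraries of 0 h or 4 h, the groups with the largest median SD (0.267 and 0.270). The 3 counts that stayed within 1.5 times use none of these. The spread shared over all groups may therefore understate that of these libraries. The interaction at 12 h, among the counts that moved, rose from 4 to 7, which an understated spread would not give. A replicate block gave 371 at 0 h and 35 at 4 h for EX against MT and moved no other count; over all comparisons, pair correlations ran from -0.417 to 0.568 and 7 samples were closest to their own number, 3 of them in EX against MT at 12 h, the 1 comparison in which every pair was above 0.1, so elsewhere the numbers were not taken to pair the samples, and the labels leave open whether they do. The replicate block ended the call of 6 of 98 named-gene results, not all of which were calls, and 2 of 24 list calls. Median-of-ratios scaling gave 361 at 0 h. Library weights, estimated gene by gene because the REML estimate did not converge, gave 3494, 229 and 81 for EX against MT, 7734 and 7970 for EX over time, 42 and 2788 for the interactions and 14 at all 3 times. Without the pair of MT libraries that stood apart, 193 and 17 genes were called for EX against MT at 0 and 4 h and 7 for the interaction at 12 h. An adjusted p under 0.01, stricter by construction, left 73, 16 and 10 for EX against MT, 1223 and 1731 in MT, 1004 and 1424 in EX, 8 for the interaction at 4 h and 3 at all 3 times. At least 5 FPKM in at least 3 libraries, with 14041 genes tested, gave 7 for EX against MT at 12 h, 9 and 2 for the interactions and 1 at all 3 times. Without the segment the interaction at 4 h had 11 calls. Leaving out 1 library at a time gave 85 to 3375 at 0 h, 13 to 504 at 4 h and 9 to 17 at 12 h for EX against MT, 1813 to 3104 and 2271 to 5110 in MT, 1182 to 1984 and 1742 to 3164 in EX, 10 to 37 and 4 to 1503 for the interactions, and 3 to 12 at all 3 times. For changes not fixed by construction the cause was not tested. Of 98 named-gene results 57 held under every setting tried for them. Among these 57 is CBF1 in EX against MT at 0, 4 and 12 h, which was not called and had no call to lose. Results outside the 57 lost their call at least once, most often with only the groups compared (36), and in 100 of 606 fits with 1 library left out, while 1 that was not called gained one. No filter ended 11, leaving out the pair of MT libraries 16, log2(FPKM + 0.1) 3, and the FPKM minimum of 5 ended 3 of 86. Of 24 list calls, an estimated correlation ended 23, leaving out the pair of MT libraries 9 and median-of-ratios scaling 2. With 16300000 to 18300000 fragments per library, genes under 1 FPKM rest on few fragments, and those under it in every group mean were tested only in the setting with no filter.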

Other observations

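The genes of this part were picked after their values were seen, from lists fixed without regard to them; the marker lists were set before the data were examined.

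Several single genes of phenylpropanoid and hormone metabolism changed over time, although their lists did not pass as sets. The gene hqt, whose enzyme makes chlorogenic acid, rose from 34.9 ± 7.23 to 222.6 ± 62.2 FPKM in MT (log2 2.62, limma adjusted p = 2.34e-05) and from 22.3 ± 10.5 to 224.9 ± 43.7 in EX (log2 3.35, adjusted p = 1.93e-06) by 12 h (SD, n = 3 each). MYB75, of the anthocyanin-related MYB factors, rose by log2 2.11 in MT and 2.39 in EX, while ANS, an anthocyanidin synthase gene below 3 FPKM, fell by log2 -1.35 and -0.94. A pair of abscisic acid synthesis genes rose: NCED1 went from 17.37 ± 6.34 to 149.0 ± 4.88 FPKM in MT and from 20.1 ± 3.74 to 143.0 ± 13.2 in EX, and NCED2 changed by log2 2.33 and 2.39. CYP707A2, an abscisic acid hydroxylase gene, fell in EX at 12 h (log2 -2.08, adjusted p = 0.0253) and was not called in MT (log2 -0.10, adjusted p = 0.928), and the difference between the lines did not pass (interaction log2 -1.98, adjusted p = 0.267). The gibberellin oxidase gene GA2ox2 rose by log2 1.72 in each line and the DELLA gene GAI by 0.77 and 0.85. At 12 h the flavonoid list had 4 called higher and 3 lower in MT and 5 and 1 in EX of 14 (5 and 2 in EX adjusted over the list alone), without passing as a set.

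The cytokinin oxidase genes parted: CKX1 fell by log2 -0.97 in MT and -1.57 in EX at 12 h, and CKX2 rose by 2.03 and 0.97. In every change named here as called, all 3 libraries of one time lay above all 3 of the other. The expansin gene EXP2 rose by log2 3.0 in MT and 2.93 in EX at 12 h, and JRE4, a regulator of glycoalkaloid genes, by 3.32 and 3.22.

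Marker lists of other tissues and of handling passed in no comparison. The lowest camera adjusted p of any comparison was 0.0694 for reproductive organs, 0.0741 for cell division and histones, 0.133 for trichomes, 0.153 for wounding and handling, 0.295 for xylem and lignin and 0.381 for epidermis and cuticle. Lists for phloem and for meristem genes had too few tested members.

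In the authors' deposited table, 15211 genes had a q-value under 0.05 for EX against MT at 0 h, 13668 at 4 h and 9978 at 12 h, where limma called 567, 53 and 24. The authors' deposited table has 1085 genes higher and 1148 lower at 0 h when a change of at least 1 log2 unit is also asked for. Its log2 ratios correlated with the limma fold changes across genes at r = 0.861 at 0 h, 0.835 at 4 h and 0.807 at 12 h, and between 0.894 and 0.914 for the time courses. For many genes the authors' deposited table gives a q-value below the p-value of the same gene, so its q-values were not used as a test here.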
